A study of Caenorhabditis elegans with 48 samples.

How the data were processed

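Messenger RNA was measured by polyA-selected, directional RNA sequencing in 48 libraries of young adult Caenorhabditis elegans, 3 replicates in each of 16 groups. Per the labels, 4 strains were grown for 51 h and kept for 2 h on plates with auxin or with its solvent ethanol, and then either held at 20 °C or heat shocked at 34 °C for 30 min. The labels number the replicates and do not state whether libraries with the same number shared a culture, a day or a sequencing run, so how separate the replicates are is unknown.

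STAR, featureCounts and edgeR are named in the submitters' processing notes without versions, together with the genome builds WBcel235 and ce11. The authors deposited for each strain a table of normalised values on a log2 scale, with 1 column per library. The values have the form of log2 CPM (counts-per-million) with a prior count of 2 reads, because the lowest value of each table, taken back to the linear scale, is an offset of 0.1155 to 0.1195 CPM, which is 2 reads of an average library. The authors also deposited a table of auxin against ethanol after heat shock for each strain, whose logFC and logCPM columns are log2 values, whose LR column is a likelihood ratio score, and whose PValue and FDR columns are p-values per the file headers. Each strain's table was normalised separately by the authors, and the tables list between 12450 and 12801 genes; every listed gene had over 1 CPM in at least 1 library.

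The deposited log2 values were converted to linear CPM by removing the log and subtracting the table's offset. In every library 100% of the resulting values lay within 0.05 of a whole number of reads, so they are counts of reads. Their totals over the listed genes were 9000611 to 24025791 reads per library. Reads outside the listed genes are not included. A count of 3 reads, the largest that a count of 0 allows at 95% confidence, corresponds to 0.127 to 0.478 CPM depending on the library. Such floors cover counting error only, since reads of amplified libraries are not independent molecules. The planned analysis assumed linear deposited values, and the conversion to the linear scale was added after the files showed a log2 unit. Because the deposited unit is a log value and not a count, neither of the planned count models was run on the recovered reads; limma-voom on those reads was added in their place.

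Genes with a mean of at least 1 CPM over the 12 libraries of a strain were tested: 11878 in CA1200, 12010 in JTL611, 12184 in CA1199 and 12228 in JTL621. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a mean-variance trend, group means fitted over the 12 libraries of the strain, two-sided moderated tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. All fold changes are therefore on the log2(CPM + 1) scale, which understates the change of genes with low values. In each strain 5 contrasts were made: heat shock on ethanol, heat shock on auxin, auxin with heat shock, auxin without heat shock, and the interaction of auxin and heat. The auxin effect after heat shock was also compared between strains, JTL611 against CA1200, JTL621 against CA1199 and JTL611 against JTL621, in a joint fit over 24 libraries of genes tested in both strains. CPM values are given as mean ± SD over 3 libraries and log2 fold changes with their SE from the limma fit.

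For 30 gene lists fixed before the data were examined, covering heat shock proteins, chaperones, proteolysis, stress and detoxification genes, germline and sperm genes and markers of tissues, the text gives the members called over all genes and, where stated, the count adjusted over the list alone. Lists were tested as sets with camera in limma, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data; 272 of the list tests over all comparisons passed with the preset value and 22 with the estimate. Genes named in the text were chosen by a rule fixed in advance: hsf-1; up to 3 called members of smallest adjusted p of each list; and the 6 called genes of largest and of smallest log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the groups. Genes named outside that rule are said to be so. Gene names, positions and biotypes came from the Ensembl annotation, release 115, of WBcel235.

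Whether replicate numbers pair the samples was checked from the correlation of the deviations of same-numbered libraries from their group means, before any blocked fit was compared; this is a pattern in the values, as the labels state no pairing. The correlation exceeded 0.1 for all 3 pairs in every contrast of 2 groups in CA1200 (0.115 to 0.448), in the heat response on ethanol (0.237 to 0.569), the heat response on auxin (0.273 to 0.567) and the auxin effect without heat shock (0.306 to 0.664) of JTL611, in the heat response on auxin of CA1199 (0.175 to 0.498), and in the heat response on ethanol (0.128 to 0.308) and the auxin effect without heat shock (0.102 to 0.575) of JTL621. In these contrasts a blocked count is given beside the main count where the block moved it by over 1.5 times.

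Alternatives were a pseudocount of 0.25, no filter on low values, quantile normalisation, median-of-ratios rescaling, the replicate number as a block, a fit to only the libraries compared, and leaving out each library in turn. Fits to the deposited log2 values without conversion and limma-voom were added after seeing the data, and the library with the highest share of ribosomal RNA was chosen after seeing the data for a separate look. The fitting steps were tested on simulated counts with gene means and typical spreads taken from JTL611, and from CA1200 for the difference between strains. Each count was drawn independently. The simulation thus held no replicate effect, no correlation between genes and no gene more variable than is typical for its level. Its shares do not cover these features of real libraries. For auxin with heat shock, 88% of genes changed 2-fold and 100% of genes changed 4-fold were recovered. Of the genes called there, 4.08% were false, with 12016 genes tested. For the interaction these shares were 73%, 96% and 5.06%. For the difference from CA1200 they were 79%, 98% and 3.83%, with 11761 genes tested. Simulated groups with no change gave 0 calls. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All 48 libraries were kept except in the alternatives that leave out 1.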

Results

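Gene expression was profiled in 4 strains of C. elegans that carry TIR1, a plant F-box protein that marks degron-tagged proteins for destruction when auxin is present. CA1200 and JTL611 express TIR1 in the soma, and CA1199 and JTL621 express it in the germline. In JTL611 and JTL621 the heat shock transcription factor HSF-1 carries an auxin-inducible degron and GFP, whereas CA1200 and CA1199 have no tagged protein and serve as controls for auxin itself. Each strain had 12 libraries. There were 3 for each combination of auxin or ethanol plates with 20 °C or heat shock at 34 °C for 30 min. Reads on listed genes ranged from 9000611 (JTL621, auxin with heat shock, replicate 2) to 24025791 (CA1199, auxin with heat shock, replicate 3). Ribosomal RNA genes took 34.5% of the counts in the library with the fewest such reads, against a median of 8.26% over all libraries. The comparisons ask which genes respond to heat, how that response depends on HSF-1 in the soma or the germline, and what auxin does alone.

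The hsf-1 transcript averaged between 30.4 ± 9.46 CPM (SD, n = 3; JTL621, auxin with heat shock) and 51.8 ± 6.27 CPM (CA1200, ethanol with heat shock) over the 16 groups and was called in none of the contrasts by limma. The degron acts on the protein, so this transcript neither checks the plate labels nor measures depletion.

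Heat shock on ethanol plates raised the inducible heat shock protein genes in all 4 strains. Transcripts of hsp-70, a heat-inducible Hsp70 chaperone, went from 1.64 ± 2.00 to 797 ± 130 CPM (SD, n = 3) in CA1200, from 0.210 ± 0.183 to 294 ± 57.7 in JTL611, from 2.04 ± 1.5 to 836 ± 118 in CA1199 and from 2.00 ± 3.03 to 607 ± 22.8 in JTL621. All 9 members of the inducible list were called in each strain, and 9 of 9 adjusted over the list alone, with median log2 fold changes of 8.15, 8.09, 7.89 and 8.13 in CA1200, JTL611, CA1199 and JTL621. The log2 rise of hsp-70 was 8.48 (SE 0.35), 7.92 (SE 0.17), 8.21 (SE 0.28) and 8.13 (SE 0.45) in the same order, and that of F44E5.4, an Hsp70 gene, 10.17, 10.53, 8.37 and 9.32. The list test held with an estimated correlation in CA1200 (adjusted p = 0.0299), JTL611 (0.00377) and JTL621 (0.0388) but not in CA1199 (adjusted p = 0.0942 with an estimated correlation). The pairs T27E4.8 and T27E4.2, T27E4.3 and T27E4.9, and F44E5.4 and F44E5.5 are near-identical copies whose reads were nearly equal in every strain. The largest difference was 9.01%, over libraries in which the pair passed a minimum number of reads. The level of each copy is thus uncertain. The 9 members are therefore not 9 separate measurements. Here and below, both copies of a pair enter the tests of this list and the counts of called genes.

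Among constitutive chaperones and co-chaperones, 6, 3, 4 and 4 of 17 genes rose in CA1200, JTL611, CA1199 and JTL621, and 6, 3, 6 and 5 adjusted over the list alone. The Hsp110 gene hsp-110 went from 593 ± 27.1 to 1740 ± 84.9 CPM in CA1200 and from 585 ± 29.4 to 1130 ± 126 CPM in JTL611, and the Hsp40 gene dnj-13 rose by log2 1.30 (SE 0.06) and 0.86 (SE 0.08). The BAG-domain co-chaperone gene unc-23 rose by 2.50 in CA1200, 1.69 in JTL611, 2.26 in CA1199 and 1.88 in JTL621. Adjusted p values of this list with an estimated correlation were 0.167, 0.239, 0.121 and 0.0388 in the same order. Among other small heat shock proteins 1 of 7, 1 of 8, 3 of 7 and 1 of 7 rose (1, 1, 3 and 2 adjusted over the list alone), and none of the 14 CCT chaperonin and prefoldin genes was called in any strain.

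Over the genome 1573 genes were called in CA1200 (681 up, 892 down), 779 in JTL611 (278 up, 501 down), 2231 in CA1199 (480 up, 1751 down) and 1219 in JTL621 (311 up, 908 down). Of 11673 genes tested in every strain, 132 rose and 303 fell in all 4, and 0 were called up in at least 1 strain and down in another. The overlap between strains, which share no library, was larger than independent lists give, for example 197 rising genes in CA1200 and JTL611 against 14.9. Genes that fell in all 4 strains included asp-13, which encodes an aspartic protease (log2 −3.27, −3.35, −2.74 and −2.45), T11G6.3 (−2.11, −1.73, −1.86 and −2) and R09B5.11 (−1.85, −1.85, −1.87 and −1.49). The count in JTL611 was 1261 with the replicate block and 283 in a fit to only the libraries compared, 449 without replicate 2 and 491 without replicate 3 of the unheated ethanol plates. It was 993 in CA1200 without replicate 2 and 997 without replicate 3 of its heat-shocked ethanol plates, and 614, 652, 684, 703 and 773 in JTL621 without heat-shocked replicate 1 or 2 or unheated replicate 1, 2 or 3. A fit to only the libraries compared called 1453 genes in CA1199 and 2659 in JTL621, and quantile normalisation called 684 up and 1335 down in CA1199.

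Of the UDP-glucuronosyltransferase (ugt) genes, whose products conjugate small molecules, 19 of 48, 11 of 50, 29 of 51 and 25 of 52 fell with heat on ethanol in CA1200, JTL611, CA1199 and JTL621, and 1, 4, 3 and 4 rose. Adjusted over the list alone, 24, 14, 36 and 35 fell and 3, 4, 3 and 4 rose. The fall was −1.54, −1.49, −1.53 and −1.59 for ugt-16 and −0.96 (SE 0.08), −1 (SE 0.10), −1.29 (SE 0.15) and −1.32 (SE 0.16) for ugt-47. The list test held with an estimated correlation in CA1200 (adjusted p = 0.016) and JTL611 (0.0384) but not in CA1199 (adjusted p = 0.16) or JTL621 (0.118). Cytochrome P450 (cyp) genes fell in 8 of 39, 2 of 41, 12 of 43 and 11 of 44 cases (8, 2, 13 and 20 adjusted over the list alone), with cyp-13A2 at −0.98, −0.87, −1.49 and −1.18. Their adjusted p was 0.422, 0.284, 0.293 and 0.0649 with an estimated correlation. Of the glutathione S-transferase (gst) genes 1 rose and 2 fell of 24 in CA1200, 0 of 24 were called in JTL611, 4 rose and 6 fell of 23 in CA1199, and 1 rose and 3 fell of 25 in JTL621. Adjusted over the list alone the falls were 2, 0, 8 and 6.

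Of 7 pharynx markers 5, 3, 7 and 6 rose with heat on ethanol in CA1200, JTL611, CA1199 and JTL621 (7, 6, 7 and 7 adjusted over the list alone), with a troponin T gene of the pharynx, tnt-4, up by 1.34, 1.32, 1.78 and 1.81. Body wall muscle markers rose in 5, 1, 0 and 4 of 11 cases (10, 4, 0 and 10 adjusted over the list alone). Intestine markers fell in 6, 4, 7 and 4 of 10 cases (6, 6, 7 and 6 adjusted over the list alone), with the peptide transporter gene pept-1 at −0.88, −0.94, −1.26 and −1.17. Neuron markers fell in 6, 3, 10 and 7 of 16 cases (9, 6, 13 and 11 adjusted over the list alone), among them ida-1, at −0.83 (SE 0.14) in CA1200. None of these lists passed with an estimated correlation: adjusted p was 0.263, 0.274, 0.199 and 0.09 for pharynx, 0.295, 0.423, 0.445 and 0.316 for muscle, 0.263, 0.239, 0.202 and 0.39 for intestine, and 0.186, 0.284, 0.121 and 0.316 for neurons. Without replicate 2 of the unheated ethanol plates of JTL611 the limma adjusted p was 0.0567 for tnt-4 and 0.0571 for ida-1.

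Histone genes rose in 5 of 38, 4 of 41, 7 of 34 and 13 of 43 cases (5, 7, 7 and 14 adjusted over the list alone), with his-41 going from 19.8 ± 1.47 to 78.4 ± 3.5 CPM in CA1200. The sperm gene spe-36 rose by 2.32, 2.89, 2.55 and 2.63, and spe-49 by 1.27, 2.11, 1.67 and 2.22. They were among 2 of 23, 2 of 23, 4 of 24 and 2 of 24 spermatogenesis genes that rose, the same counts adjusted over the list alone. The cuticle collagen gene dpy-17 rose by 1.45, 2.13, 1.40 and 1.67, while few other collagens were called (4 of 97, 2 of 114, 1 of 111 and 2 of 118 rose; 1, 0, 4 and 2 fell). Of 6 vitellogenin genes 5 fell in CA1199 (6 adjusted over the list alone, adjusted p = 0.293 with an estimated correlation); in JTL611 this list had a median of −0.47, with an adjusted p at the preset correlation of 0.0876 that became 0.0235 with the replicate block, and 0.603 with an estimated correlation. In JTL611 the metal-response list rose in 2 and fell in 1 of 3 cases, with an adjusted p at the preset correlation of 0.0312 that became 0.0808 with the block, and 0.284 with an estimated correlation.

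The other lists had few members called over all genes after heat shock on ethanol, given here for CA1200, JTL611, CA1199 and JTL621. Their counts on ethanol adjusted over the list alone are not given and may be larger. Ubiquitin genes rose in 2, 1, 1 and 1 of 10 cases, proteasome genes in 1, 0, 3 and 0 of 32, meiosis genes in 3, 0, 2 and 0 of 25, antimicrobial genes in 1, 0, 0 and 1 of 8 or 9, and regulators of HSF-1 in 1, 0, 1 and 0 of 4. Epidermis markers fell in 2, 1, 2 and 2 of 10 or 11 cases, intracellular pathogen response genes in 1, 0, 1 and 0 of 4 or 5, and mitochondrial chaperones in 0, 1, 1 and 0 of 11. Of 19 endoplasmic reticulum stress genes 1, 0, 1 and 1 rose and 0, 0, 4 and 0 fell. Of 20 germ granule genes 1, 0, 1 and 0 rose and 1, 1, 0 and 0 fell, and 1 oxidative stress gene fell in CA1199. No ribosomal protein, major sperm protein or oogenesis gene was called by limma in any strain. None of these lists passed with an estimated correlation, and on auxin plates the only further one to pass was that of ubiquitin genes in CA1200 (3 of 10 rose, 6 adjusted over the list alone, adjusted p = 0.0416).

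Heat shock on auxin plates gave 2308 calls in CA1200 (1137 up, 1171 down), 917 in JTL611 (269 up, 648 down), 1994 in CA1199 (467 up, 1527 down) and 2142 in JTL621 (760 up, 1382 down). The 9 inducible heat shock protein genes again rose in the 3 strains other than JTL611, with medians of 8.79 in CA1200, 8.55 in CA1199 and 8.87 in JTL621. In JTL611 the median was 2.48, with 8 of 9 called (9 adjusted over the list alone), and hsp-70 reached 1.33 ± 0.306 CPM after heat shock. The adjusted p of this list with an estimated correlation was 0.0416 in CA1200, 0.0307 in JTL611, 0.064 in CA1199 and 0.149 in JTL621. Of 29 major sperm protein genes 20 rose in JTL621 (29 adjusted over the list alone) and 9 fell in CA1200 (27 adjusted over the list alone). Their adjusted p was 0.405 and 0.519 with an estimated correlation. The JTL621 group holds the library with 34.5% ribosomal RNA, without which 1619 genes were called in JTL621. In CA1200 heat-shocked auxin replicate 3 had 18.5% ribosomal RNA, against 8.16% and 7.33% in replicates 1 and 2. Major sperm protein genes took 0.132% of its counts, against 0.198% and 0.164%.

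The count on auxin in JTL611 was 1471 both with the replicate block and in a fit to only the libraries compared. It was 553, 511 and 584 without heat-shocked auxin replicate 1, 2 or 3, and 447 and 515 without unheated auxin replicate 2 or 3. Leaving out unheated auxin replicate 1 or 3 gave 1378 and 1306 in CA1200, and leaving out unheated auxin replicate 2 or 3 gave 1148 and 1395 in JTL621. In CA1199 the count was 1293 and 1221 without heat-shocked auxin replicate 2 or 3 and 1251 without unheated auxin replicate 3. Fits to only the libraries compared gave 3301 in CA1199 and 587 in JTL621, and quantile normalisation called 565 up and 1111 down in CA1199.

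**Figure D1:**
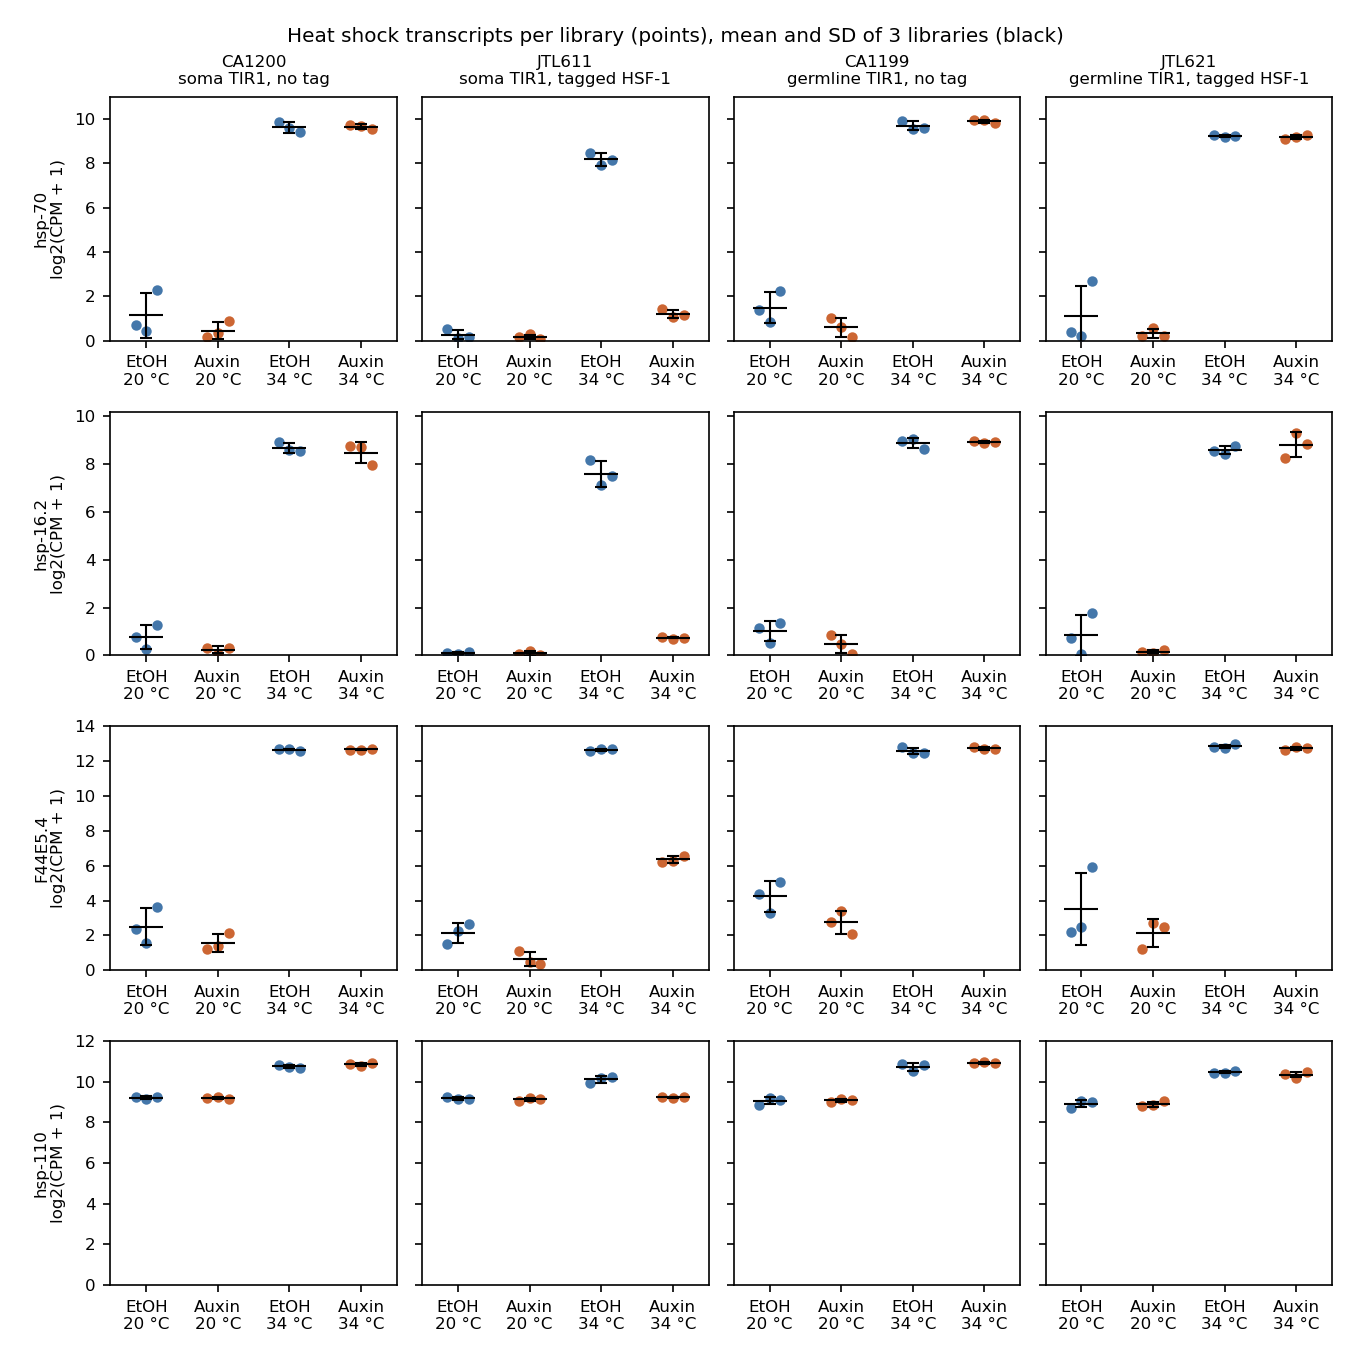
Level of hsp-70, hsp-16.2, F44E5.4 and hsp-110 in each of the 48 libraries as log2(CPM + 1), by strain, plate and temperature; points are libraries and bars the mean ± SD over 3. After heat shock hsp-70 lay at 294 ± 57.7 CPM on ethanol and at 1.33 ± 0.306 CPM on auxin in JTL611.

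Auxin lowered the heat-shocked level of 28 genes in JTL611, in which HSF-1 is tagged in a strain with somatic TIR1. All 9 inducible heat shock protein genes were among them (9 adjusted over the list alone), with a median log2 change of −6.77. After heat shock hsp-16.2 was at 200 ± 75.6 CPM on ethanol and 0.673 ± 0.0374 CPM on auxin (SD, n = 3), hsp-16.41 at 247 ± 94.1 and 0.718 ± 0.156, T27E4.8 at 752 ± 228 and 5.75 ± 1.40, and F44E5.4 at 6490 ± 296 and 82.2 ± 11. Of 17 constitutive chaperone genes 3 fell (3 adjusted over the list alone): hsp-110 from 1130 ± 126 to 605 ± 12.5 CPM, dnj-13 from 303 ± 9.24 to 156 ± 8.09 and unc-23 from 82.0 ± 12.9 to 37.5 ± 1.07. On auxin the heat-shocked levels of hsp-110 and dnj-13 were close to their unheated levels on ethanol, 585 ± 29.4 and 167 ± 13.2 CPM. Against unheated auxin plates dnj-13 still rose by log2 0.22. Its interaction of auxin and heat, −0.65, was not called (adjusted p = 0.0589, limma). The adjusted p of hsp-70 was 4.88e-10 and that of hsp-110 0.00019 (limma), and that of the lists with an estimated correlation was 0.000149 for the inducible genes and 0.0562 for the constitutive chaperones.

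A further 16 genes, named here after their values were seen, fell in the same comparison and are on neither list. They include the patched-related gene ptr-18 (−2.79, SE 0.24), the sterol-sensing domain gene scp-1 (−1.87, SE 0.08) with its neighbour ttll-12 (−0.89, SE 0.06), the poly(A) polymerase family gene tent-5 (−1.57, SE 0.12), the chromatin remodelling gene nurf-1 (−0.67, SE 0.07), R107.5 (−1.76), R11A5.3 (−2.85) and Y94H6A.10 (−3.81, SE 0.17). The genes scp-1 and ttll-12 lie on chromosome II at 9334014 to 9338896 and 9338997 to 9341394 (WBcel235). They are on the same strand. T27E4.1 (−1.60), on chromosome V at 9092345 to 9094357, lies beside the hsp-16 cluster that runs from T27E4.8 at 9087293 to T27E4.2 at 9090604.

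The interaction of auxin and heat was called for 24 genes in JTL611, all with a smaller heat response on auxin. It was −6.88 (SE 0.24) for hsp-70, −6.83 (SE 0.29) for hsp-16.2, −0.83 (SE 0.12) for hsp-110 and −1.02 (SE 0.16) for unc-23, with limma adjusted p of 3.3e-08, 1.07e-07, 0.0152 and 0.0192. The list medians were −6.39 for the inducible genes (9 of 9 called, 9 adjusted over the list alone, adjusted p = 5.04e-05 with an estimated correlation) and 0.00 for the constitutive chaperones (2 of 17 called, 3 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation; 0.0346 with the preset value). All 24 lay among the 28 genes lowered after heat shock, where independent lists would share 0.056. Both contrasts use the same heat-shocked libraries, so this is not separate evidence. limma-voom called 15 genes, without unc-23 (adjusted p = 0.0544) and T27E4.9 (0.334). The calls of hsp-110 and unc-23 were lost in some fits with 1 library fewer, where the interaction was −0.85 to −0.8 and −1.04 to −1. Without heat-shocked auxin replicate 1, 2 or 3 adjusted p was 0.0543, 0.0679 and 0.0637 for hsp-110 and 0.0853, 0.0799 and 0.0637 for unc-23. Without unheated auxin replicate 2 or 3 it was 0.0722 and 0.0734 for hsp-110 and 0.0722 and 0.0725 for unc-23, without unheated auxin replicate 1 it was 0.0742 for unc-23, and without unheated ethanol replicate 2 or 3 it was 0.0681 and 0.0743 for hsp-110. Quantile normalisation gave 0.122 for hsp-110.

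The auxin effect after heat shock was also lower in JTL611 than in strains with untagged HSF-1 or with germline TIR1. Against CA1200, 27 genes differed, all lower, and against JTL621, 26 genes, all lower; 25 were shared, in comparisons that use the same JTL611 libraries (0.0601 for independent lists). The difference was −7 for hsp-70, −6.65 for hsp-16.2 and −1 for hsp-110 against CA1200, and −6.92, −7.07 and −0.76 against JTL621. The inducible list was called in 9 of 9 members in each (9 adjusted over the list alone), with adjusted p of 4.91e-07 and 5.93e-05 with an estimated correlation. The constitutive chaperones were called in 3 of 17 against CA1200 and 2 of 17 against JTL621 (3 in each adjusted over the list alone), with adjusted p of 0.00717 and 0.63 with an estimated correlation. The hsp-110 difference against JTL621 had an adjusted p of 0.484 with quantile normalisation, 0.0608 with median-of-ratios rescaling and 0.168 in a fit to only the libraries compared. It was also above the threshold without JTL611 heat-shocked auxin replicate 2 (0.072) or 3 (0.0599) or ethanol replicate 2 (0.0718) or 3 (0.0896), and without JTL621 heat-shocked auxin replicate 3 (0.0927) or ethanol replicate 1 (0.0705) or 2 (0.0717).

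In JTL621, with tagged HSF-1 and germline TIR1, no heat shock gene was called lower on auxin. After heat shock hsp-70 was at 607 ± 22.8 CPM on ethanol and 588 ± 32 on auxin (SD, n = 3), hsp-16.2 at 384 ± 46.9 and 468 ± 165, and hsp-110 at 1430 ± 48.9 and 1310 ± 115. In CA1199 without the tag hsp-70 was at 836 ± 118 and 962 ± 45.1 CPM. limma called 0 genes in the interaction of auxin and heat in JTL621, CA1199 and CA1200. At an unadjusted p under 0.05 there were 234 of 12228, 170 of 12184 and 185 of 11878 genes. It also called 0 in the difference between JTL621 and CA1199 (1230 of 12047). With no change at all a share of 0.05 would pass. The interaction counts are below that share and 1230 is above it. limma-voom called 0 in each of these comparisons. Whole animals were sequenced, so a change confined to germ cells is diluted by somatic transcripts, and leaving out 1 library gave at most 1 call in CA1200 (unheated auxin replicate 3) and 2 in JTL621 (unheated auxin replicate 2).

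Of 114 genes with a log2 rise of at least 1 in both CA1200 and CA1199 on ethanol, 97 were tested in JTL611. The filter takes the mean over the 12 libraries of a strain, so losing the response on auxin makes a gene more likely to be left out. Y53F4B.8, with a rise of 3.21 in CA1200 and 3.81 in CA1199, was among those not tested in JTL611. The values for JTL611 cover the tested genes only. The median ratio of the log2 heat response on auxin to that on ethanol was 0.868 in JTL611 (SD 0.12 over 3 libraries), 1.05 in JTL621 (SD 0.0865, 109 genes), 1.02 in CA1200 and 1.03 in CA1199. The SDs of ratios cover only the 3 heat-shocked auxin libraries, with the means of the other groups held fixed. They leave out the spread of those groups. Being a ratio of log2 changes, the median ratio is not the share of the induced transcript that remained. In JTL611, 32 of the 97 genes had a ratio under 0.5 and 35 had a ratio above 1, and 68 were still called up on auxin against 89 on ethanol. Low ratios were those of the inducible heat shock protein genes (median 0.28, SD 0.0317, 9 genes), the constitutive chaperones (0.251, 3 genes), scp-1 (−0.03) and ptr-18 (−0.07). These ratios do not rank genes of unlike induction by how much they lost. F44E5.4, at log2 10.53 on ethanol and 5.73 on auxin in JTL611, had a ratio of 0.54. The ratio of dnj-13, at 0.86 and 0.22, was 0.25. Ratios near 1 were those of the histone gene his-41 (1.13), spe-36 (1.15), dpy-17 (0.95) and, chosen after their values were seen, kreg-1 (1.08), zip-10 (1.11), adh-1 (1.04) and the noncoding RNA gene tts-1 (1.12). JTL611 expresses TIR1 in the soma and whole animals were sequenced, so a kept response may come from germ cells. The tissue was not determined. In JTL611 after heat shock kreg-1 was at 17.6 ± 1.93 CPM on ethanol and 20.0 ± 6.42 on auxin, from 0.516 ± 0.332 and 0.344 ± 0.208 without heat. The 4 pharynx markers had a median ratio of 0.999 in JTL611, with an SD of 0.462 and values of 0.686 to 1.51 over the libraries. Of these tnt-4 was at 0.63, and 1 of 4 was called up on auxin against 2 on ethanol in JTL611. In JTL621 the median of the pharynx markers was 0.654 (SD 0.121). Among the genes that rose by log2 2 or more in both control strains the median ratio in JTL611 was 0.536.

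**Figure D2:**
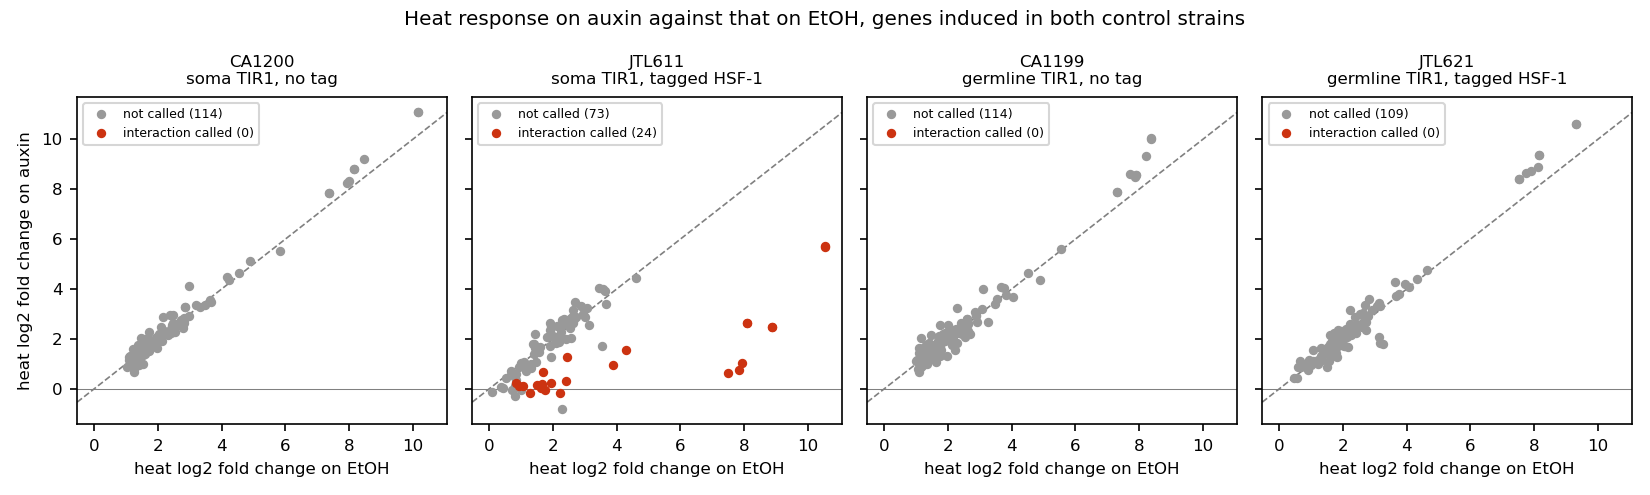
Log2 heat response on auxin plates against that on ethanol plates, for genes induced in both control strains, by strain, with the line of equal response and genes with a called interaction in red. In JTL611 the median ratio of the log2 responses was 0.868 and 32 of 97 genes lay under 0.5.

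Auxin raised 4 detoxification genes, gst-21, gst-35, ugt-22 and ugt-16, in every strain, with and without tagged HSF-1, and at both temperatures. After heat shock limma called 7 higher genes in CA1200, 11 in JTL611, 30 in CA1199 and 21 in JTL621, and at 20 °C 21, 10, 26 and 21; none was lower except the 28 genes above and Y94H6A.10 at 20 °C, both in JTL611. The cytochrome P450 gene cyp-35A2 rose at 20 °C from 11.3 ± 5.02 to 92.0 ± 37.7 CPM in CA1200, from 20.0 ± 5.89 to 118 ± 40.7 in CA1199 and from 34.7 ± 5.06 to 157 ± 37.2 in JTL621. Over the 8 comparisons its log2 change was 2.12 to 2.91 and that of cyp-35C1 2.26 to 3.04, each called in 7. In CA1200 after heat shock neither was called (adjusted p = 0.168 for both, limma). In total 44 genes rose in at least 1 comparison, and 24 of these were cyp, ugt or gst genes, as were 13 of the 18 that rose in at least 4. The strains share no library, and 20 genes rose after heat shock in both CA1199 and JTL621, against 0.0523 for independent lists.

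After heat shock 0, 3, 6 and 5 of the cyp genes rose in CA1200, JTL611, CA1199 and JTL621 (7, 7, 9 and 9 adjusted over the list alone), 3, 3, 7 and 6 of the ugt genes (10, 7, 12 and 11) and 2, 2, 3 and 3 of the gst genes (3, 3, 5 and 7). At 20 °C the counts were 4, 3, 8 and 7 for cyp (9, 7, 9 and 7 adjusted over the list alone), 8, 4, 6 and 5 for ugt (18, 5, 15 and 9) and 2, 2, 4 and 3 for gst (3, 3, 6 and 4). With an estimated correlation the ugt list held in CA1200 (adjusted p = 0.0326 after heat shock, 6e-04 at 20 °C) and JTL611 (0.0426 and 0.00404), and the cyp list in JTL611 (0.0459 and 0.0249). It did not hold for the cyp list in CA1200 (adjusted p = 0.378 and 0.163), CA1199 (0.342 and 0.0884) or JTL621 (0.0502 and 0.0897), the ugt list in CA1199 (0.342 and 0.142) or JTL621 (0.623 and 0.405), or the gst list in any strain, where its adjusted p was between 0.0884 and 0.861. With the replicate block the counts at 20 °C were 56 in CA1200 and 17 in JTL611, and 21 in CA1200 after heat shock; limma-voom called 3 in the latter. Leaving out heat-shocked ethanol replicate 2 or 3 or auxin replicate 1 or 2 gave 3, 2, 3 and 2 in CA1200, and leaving out heat-shocked ethanol replicate 2 or auxin replicate 3 gave 13 in JTL621. At 20 °C the count in CA1200 was 13 without ethanol replicate 2 or 3, 11 without auxin replicate 1 or 2 and 45 without auxin replicate 3, and a fit to only the libraries compared gave 4 in JTL611.

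**Figure D3:**
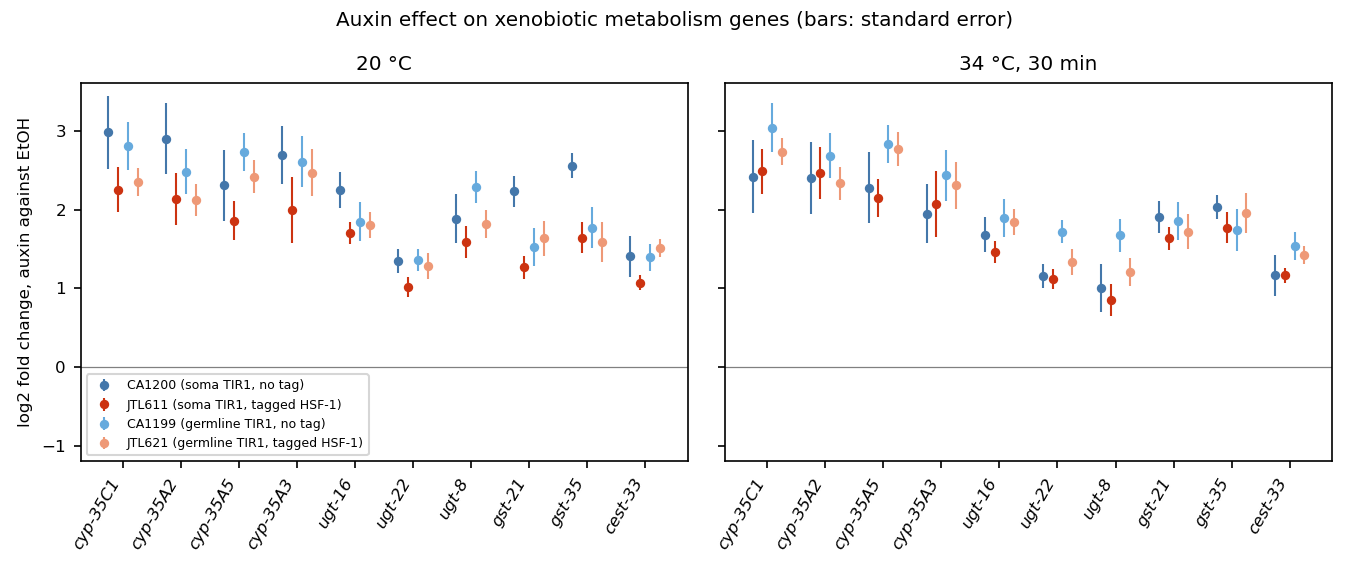
Log2 change on auxin against ethanol, with its SE, of 10 detoxification genes in the 4 strains at 20 °C and after heat shock at 34 °C. The changes of cyp-35C1 lie between 2.26 and 3.04 in all 8 comparisons.

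At 20 °C Y94H6A.10 was the only gene that auxin lowered by limma, in JTL611, from 68.7 ± 17.7 to 9.11 ± 0.424 CPM (SD, n = 3; log2 −2.75, SE 0.17, adjusted p = 2.3e-05). In CA1200 it was at 61.1 ± 3.32 CPM on ethanol and 53.0 ± 15.9 on auxin, and in JTL621 at 155 ± 14.7 and 131 ± 59.8. Inducible heat shock protein genes had medians of −0.77, −0.38, −0.67 and −0.78 on auxin at 20 °C in CA1200, JTL611, CA1199 and JTL621, and no member was called over all genes; adjusted over the list alone 6, 2, 9 and 0 fell. The adjusted p of the list with an estimated correlation was 0.163 in CA1200, 0.0715 in JTL611, 0.121 in CA1199 and 0.405 in JTL621. Unheated on ethanol, F44E5.4 was highest in replicate 3 of every strain, at 11.3, 5.2, 32.3 and 59.7 CPM in CA1200, JTL611, CA1199 and JTL621.

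The authors' deposited tables of auxin against ethanol after heat shock list genes with an FDR under 0.05 in each strain: 52 up and 2 down in CA1200, 41 up and 63 down in JTL611, 55 up and 5 down in CA1199, and 42 up and 0 down in JTL621. All 7, 39, 30 and 21 genes called here by limma were among them with the same sign.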

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

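All tests on regrouped libraries and on the 2 patterns weighed below were chosen after the results were seen. Some were also changed after their first values were seen: the test of the tag from a median (−0.27 against −0.79) to a count (4), the background of the overlap from all genes to heat-induced genes, and the chi-square by adding the spread of the heat-shocked level. The auxin effects in the next 2 paragraphs and the heat response on ethanol weighed first stand out because they differed between groups in a test of the difference itself; comparisons with 0 calls are given beside them. The unheated replicate 3 weighed last was noticed in the values: groups of 3 libraries were not tested for a library far from the others.

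The auxin effect differed between temperatures in JTL611 for 24 genes. The interaction was −6.88 for hsp-70, −6.83 for hsp-16.2, −7.06 for hsp-16.41, −6.39 for T27E4.8 and T27E4.2, −5.44 for T27E4.9, −0.83 for hsp-110 and −1.02 for unc-23, with a median of −6.39 over the inducible list. The unheated levels of hsp-16.2 and hsp-16.41 in JTL611 were under the floor of 3 reads in every library, so their interaction depends on the pseudocount. Plates were exchanged among the libraries of each temperature, in 100 groupings that include the real 1. At least as many calls came from 8 of the 100, up to 26. All 8, the real grouping among them, keep the real plates among heat-shocked libraries. Groupings without those plates gave 0. Since those 8 still hold the auxin effect after heat shock, their share says nothing about chance. The interactions of CA1200, CA1199 and JTL621 had 0 calls by limma (185 of 11878, 170 of 12184 and 234 of 12228 at an unadjusted p under 0.05) and 0 by limma-voom. Against a count of 0 all 100 groupings give as many by construction, so they say nothing about chance; the highest gave 48, 159 and 3 calls.

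The auxin effect after heat shock differed between JTL611 and CA1200 for 27 genes: hsp-70 by −7, hsp-16.2 by −6.65, hsp-16.41 by −6.90, T27E4.8 and T27E4.2 by −6.50, F44E5.4 by −6.30, hsp-110 by −1, dnj-13 by −0.91 and unc-23 by −1.12, with medians of −6.50 over the inducible list and −0.10 over the constitutive chaperones. Of 100 groupings, the real 1 included, 7 gave at least as many, up to 55. All 7, the real grouping among them, keep the real plates in JTL611, and with them the effect. Without those plates the highest was 2. Their share says nothing about chance. Between JTL611 and JTL621 it differed for 26 genes: hsp-70 by −6.92, hsp-16.2 by −7.07, hsp-16.41 by −7.36, T27E4.8 and T27E4.2 by −7.02, T27E4.3 by −6.16, T27E4.9 by −6.17, F44E5.4 by −6.18, dnj-13 by −0.83 and hsp-110 by −0.76, with a median of −6.92 over the inducible list. Here 7 of 100 gave at least as many, and 6 of these, the real grouping among them, keep the real plates in JTL611. The other gave 755, many times the real count, as a structure of the samples other than the plates would; what sets it apart was not tested. Those 6 still hold the effect and say nothing about chance, so the count of 7 does not settle it. The difference between JTL621 and CA1199 had 0 calls by limma (1230 of 12047 at an unadjusted p under 0.05) and 0 by limma-voom. Against this all 100 give as many by construction, up to 53.

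For each of the 16 contrasts of 3 against 3 libraries the real grouping alone, 1 of 10, gave its count, and 10 groupings are too few for a share under 0.05. The highest count of the others was 3 against 779 for heat on ethanol in JTL611, 1 against 11 and 2 against 26 for auxin at 20 °C in JTL611 and CA1199, 8 against 21 for auxin at 20 °C in JTL621, and 1 against 30 for auxin after heat shock in CA1199. It was 0 for the others: heat in CA1200 (1573 on ethanol, 2308 on auxin), CA1199 (2231 and 1994) and JTL621 (1219 and 2142), heat on auxin in JTL611 (917), auxin after heat shock in CA1200 (7), JTL611 (39) and JTL621 (21), and auxin at 20 °C in CA1200 (21).

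The heat response on ethanol was lower in JTL611 than in CA1200 for 9 genes, W03F9.1, aip-1, scp-1, ttll-12, ptr-18, nurf-1, tent-5, R11A5.3 and hsp-110, with a median of −0.79, named after their values were seen. Scaling is argued against, since the median was −0.71 after quantile normalisation and −0.8 after median-of-ratios rescaling; over all alternatives tried 6 (limma-voom) to 12 (replicate block) genes were called. The tag alone, with the same loss in both tagged strains, would leave JTL611 and JTL621 as far apart as CA1200 and CA1199. Of the 9 genes, 4 also had a lower heat response in JTL611 than in JTL621, the only genes called among 11871 tested. These were W03F9.1 (−0.55, SE 0.09), scp-1 (−0.82, SE 0.14), ttll-12 (−0.68, SE 0.11) and nurf-1 (−0.74, SE 0.11). CA1200 minus CA1199 gave −0.02 (SE 0.09), −0.13 (SE 0.15), −0.13 (SE 0.13) and −0.04 (SE 0.13), with 0 genes called by limma. For these 4 genes the values argue against the tag alone as the whole cause. The others were not called there, and the 9 were chosen for a low response in the same JTL611 ethanol libraries. For the others the tag alone stays open. Whether the loss against the control differs between the 2 tagged strains was not tested. A part of the lower response may come from the tag, as all 9 were below 0 in JTL621 against CA1199 (median −0.27, ptr-18 −0.86, R11A5.3 −0.93). In that comparison 0 genes were called by limma (183 of 12047 at an unadjusted p under 0.05). Lower HSF-1 activity in the soma of JTL611 before auxin stays open: 7 of the 9 are among the 24 genes whose heat response auxin lowered, but both comparisons use the same JTL611 ethanol libraries, so 2.23 for independent lists among 97 heat-induced genes is no fair measure of it, and of the 9 inducible heat shock protein genes 3 were below 0 (hsp-70 −0.56, SE 0.44, at 294 ± 57.7 against 797 ± 130 CPM after heat shock), 0 were called by limma, and 6, which are 3 pairs of near-identical copies, were above (T27E4.8 0.73, SE 0.38; F44E5.4 0.37, SE 0.5) with lower unheated levels in JTL611 (T27E4.8 0.56 ± 0.0876 against 2.46 ± 1.2 CPM) and no higher heat-shocked levels (T27E4.8 752 ± 228 against 934 ± 59.2, F44E5.4 6490 ± 296 against 6520 ± 209); strain background and culture day were not tested.

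Unheated ethanol replicate 3 held heat shock transcripts in CA1200, CA1199 and JTL621, with medians of 0.406%, 0.494% and 0.738% of the heat-shocked level over 6 genes, as did ethanol replicate 1 of CA1199 (0.301%, excess 0.0491 to 0.199). A share of heat-shocked RNA or reads would give every gene the same excess as a percent of that level. The chi-square for equal excess was 24.1 in CA1200, 5.36 in CA1199 and 10.1 in JTL621 against a 99% point of 15.1, or 39.2, 10.3 and 18.5 with counting error only. It also passed that point in ethanol replicates 1 and 2 (41.4 and 21.8) and auxin replicates 1 and 2 (29.3 and 112) of CA1200, auxin replicate 1 (17.8) of CA1199, and ethanol replicate 1 (37.3) and auxin replicate 3 (15.7) of JTL621. Each was measured against the other unheated libraries, ethanol replicate 3 among them, so these values may partly reflect that replicate. They cannot show how the test behaves without it. In CA1200 both chi-squares of replicate 3 passed the point, but no reference free of that replicate was used here to judge them. The chi-square thus excludes such a share in none of the 3 strains. Mild heat or stress during handling was not tested and stays open.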

How the results depend on the processing

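Fits to the deposited log2 values, limma-voom and the fit without JTL621 heat-shocked auxin replicate 2 were chosen after seeing the data; the other alternatives were planned. The planned fits of whole reads with 2 count models were not run, since the deposited unit is log2.

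No named gene that was called reversed its direction under any alternative. Calls of named genes were lost in 64 cases in fits to only the libraries compared, 32 with quantile normalisation, 17 with limma-voom, 5 with median-of-ratios rescaling, 4 with the pseudocount of 0.25, 4 with the deposited log2 values, 3 with the replicate block and 0 with no filter. Leaving out 1 library left 3157 results of named genes, called or not, on the same side of the threshold; 405 calls were lost and 2 gained.

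With the replicate block the auxin effect in CA1200 had 21 calls after heat shock and 56 at 20 °C, and JTL611 had 1261 calls for heat on ethanol, 1471 for heat on auxin and 17 for auxin at 20 °C. It changed no other count by over 1.5 times, and for the interaction in JTL611 the same 24 genes were called. Blocked list tests, at the preset correlation, changed calls in paired contrasts besides those given above as follows: meiosis genes in CA1200, heat on ethanol, from 0.0417 to 0.0579; metal genes from 0.0179 to 0.0515 and collagens from 0.0627 to 0.0174 in JTL611, heat on auxin; oogenesis genes in CA1199, heat on auxin, from 0.0576 to 0.0476; ubiquitin genes from 0.0492 to 0.0566 and vitellogenins from 0.0927 to 0.036 in JTL621, auxin at 20 °C.

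Fits to only the libraries compared gave 283 calls for heat on ethanol, 1471 for heat on auxin and 4 for auxin at 20 °C in JTL611, 1453 and 3301 for heat on ethanol and auxin in CA1199, and 2659 and 587 in JTL621. These fits estimate the spread from 6 libraries, not 12. limma-voom called 3 genes for auxin after heat shock in CA1200 and 15 for the interaction in JTL611; the cause was not tested. The median ratio of log2 heat responses in JTL611 was 0.536 among genes with a log2 rise of at least 2, a set in which heat shock proteins weigh more. Of the list tests, 22 passed with the estimated correlation against 272 with the preset value.

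Leaving out 1 library, which lowers the number of samples, gave 993 to 1265 calls for heat on ethanol and 1306 to 2278 for heat on auxin in CA1200, 449 to 906 and 447 to 648 in JTL611, 1549 to 2120 and 1221 to 1565 in CA1199, and 614 to 866 and 1148 to 3028 in JTL621. For auxin after heat shock it gave 2 to 6 in CA1200, 34 to 37 in JTL611, 24 to 33 in CA1199 and 13 to 21 in JTL621. At 20 °C it gave 11 to 45, 8 to 12, 20 to 33 and 14 to 28 in the same order. The interaction had 0 to 1 in CA1200, 19 to 24 in JTL611, 0 to 0 in CA1199 and 0 to 2 in JTL621. JTL621 heat-shocked auxin replicate 2 was the library with the fewest reads on listed genes. Without it 1619 genes were called for heat on auxin and 21 for auxin after heat shock in JTL621, and 24 for the difference from JTL611. A count of 3 reads is 0.478 CPM in JTL621 heat-shocked auxin replicate 2 and 0.127 CPM in the library with the lowest such level, which limits what can be said of genes near those levels.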

Other observations

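These values were picked out after the data were seen, and no hypothesis about them was tested.

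In JTL621 sperm and histone genes rose with heat on auxin: 20 of 29 major sperm protein genes (median log2 0.79), 9 of 24 spermatogenesis genes and 17 of 43 histone genes, or 29, 11 and 23 adjusted over the list alone. None of the 3 lists passed with an estimated correlation (adjusted p = 0.405, 0.248 and 0.291). Major sperm protein genes took 0.206%, 0.113% and 0.164% of the counts in unheated auxin replicates 1, 2 and 3 and 0.188%, 0.298% and 0.239% in the heat-shocked ones. The interaction of auxin and heat in JTL621 was called by limma for 0 genes (234 of 12228 at an unadjusted p under 0.05) and by limma-voom for 0. Its heat-shocked auxin replicate 2 has 34.5% ribosomal RNA; the next highest library, CA1200 heat-shocked auxin replicate 3, has 18.5%.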
